A study of Mus musculus with 2 samples.

How the data were processed

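RNA was measured in single immune cells that had infiltrated the colon of C57BL/6 mice with experimental colitis, in 1 library labelled WT and 1 labelled CKO. The values are UMI counts per gene and cell barcode as deposited, whole numbers without normalization per the file headers. The matrix headers name Cell Ranger 6.0.1, while the submitters' processing notes name Cell Ranger 5.0.0, Seurat 3.2.3 and the mm10 genome. How cell barcodes were called is not given in the sources used here; the smallest barcode totals were 501 UMIs in the library labelled WT and 500 UMIs in the library labelled CKO. Median mitochondrial shares were 2.95 and 3.02% of UMIs, and 17833 and 19727 of 32285 genes had a UMI. How many mice each library holds is not given in the sources used here.

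Barcodes with fewer than 200 genes (11 and 36) or more than 20% mitochondrial UMIs (42 and 130) were left out, which kept 2925 and 11155. Doublets were marked by Scrublet in each library at its automatic threshold, with an expected rate of 0.8% per 1000 cells, or 2.34 and 8.92%. Scrublet marked 1 cell (0.0342%) and 213 cells (1.91%), below the expected rate in both libraries. Counts were scaled to 10000 UMIs per cell and log transformed, and both libraries were clustered together without batch correction. Clustering used 2000 variable genes and 30 principal components for all cells, 1500 and 20 within the lymphoid, myeloid and B lineage compartments, and 1000 and 15 within T-like cells, with 15 neighbours, Leiden resolution 1 and seed 0. Clusters were named from 27 fixed marker classes, with at least 3 detected markers and no other class with more markers than the named class among the top 10 genes, those detected in 20% of cells and ranked with 20 CPM added. By this rule 4 clusters were named with 0 of their own markers among the top genes: a monocyte and macrophage-like cluster led by Nos2, B-like clusters led by interferon and by heat shock genes, and the part of the Lef1 subset with interferon genes. Most clusters whose leading genes came from different classes were kept apart as mixed, and clusters without a leading class were left unnamed. A B-like cluster led within its compartment by S100a8 and S100a9 kept its name, as did a monocyte and macrophage-like cluster led there by Iglc1 and C1qa. Gene and marker lists, the classes, the rule for named genes, the lists and most alternative settings were chosen before the data were examined. The naming of mixed and unnamed clusters was not. The Lef1, Ikzf2 Cd7 and Cd8a Itgae subsets of T-like cells are not among the 27 classes and were named after genes leading their clusters in these data.

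UMIs were summed over the cells of a class in each library and given as CPM, with exact 95% Poisson intervals for sums, binomial intervals for shares and conditional intervals for ratios. These intervals treat UMIs and cells as independent draws and cover counting error only. Each group has 1 library, so no test, p-value or count of altered genes was made from cells. Against 0 counts, a bound was computed at a floor of 3 counts over the class. Shares of cells with a UMI were taken after each cell was thinned at random to 1000 UMIs.

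Genes were named by a fixed rule. Candidates had at least 50 UMIs over both libraries, at least 50 CPM in the higher library, and there at least 0.1 of the CPM of the highest named class. Gene models without a name, ribosomal and mitochondrial genes, immunoglobulin and T cell receptor segments and sex-linked genes were left out. The 12 largest and 12 smallest log2 ratios were named in T-like cells (2700 candidates), and 8 each way in the other classes with at least 200 cells in each library, which were B-like (2314) and plasma-like cells (1003). Rpa1 was read in every class, and Rpa2, Rpa3, Ripk1, Ripk3, Mlkl and Zbp1 in T-like cells. Of 612 symbols in 32 gene lists, 608 were matched. A list member was read at 20 or more UMIs, a member was counted at 1.5-fold, up to 4 members with the largest ratios were taken as examples, and a list median was set against 10000 random lists matched in 20 expression bins, with an interval from 1000 Poisson redraws.

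The steps were tested on simulated data in which known genes were altered in sums of the same depth. Each sum was drawn from the pooled profile of its class with counting error only, so the coverage of the intervals was built in. Variation between cells, subsets or libraries was not simulated. In T-like cells, with totals of 2117874 and 2955916 UMIs, 98.5% of genes altered 2-fold were read at 1.5-fold or more, 8.89% of unaltered genes were too, and intervals held 95.9% of true ratios. In B-like, plasma-like, neutrophil-like and monocyte and macrophage-like cells, 93.7, 87.5, 83.6 and 84.5% of such genes were read, and 6.71, 9.33, 27.1 and 31.6% of unaltered genes. Of 100 unaltered lists, the outer 5% of matched lists took 6 in T-like cells and 7 in monocyte and macrophage-like cells. Those lists were random genes, so they do not show how lists of genes that move together behave. Alternatives varied the filters, doublets, clustering, denominator, depth, scaling, free RNA and list minimum, and further ones were chosen after the data were seen. Software was Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.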

Results

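The series holds single-cell RNA profiles of immune cells that had infiltrated the mouse colon in experimental colitis, an induced inflammation of the large bowel. There were 2 libraries, 1 labelled WT and 1 labelled CKO, both from the C57BL/6 strain and made with the 10x 3′ gene expression kit, which counts each captured transcript by a unique molecular identifier (UMI). The library labelled WT held 2972 cell barcodes and 18627050 UMIs, with a median of 4083 UMIs and 1377.5 genes per barcode. The library labelled CKO held 11311 barcodes and 57740083 UMIs, with medians of 3338 UMIs and 1160.0 genes. After filtering, 2924 and 10942 cells were retained. With 1 library per group there was no replicate check and no test between the groups, and the label cannot be separated from the animal, the cell preparation or the library. All intervals are 95% intervals that cover counting error only, exact for sums, shares and ratios of sums, and every log2 ratio is of the library labelled CKO over the library labelled WT.

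The title of the series names loss of RPA1, so Rpa1 was examined before anything else. Rpa1 (ENSMUSG00000000751) encodes the large subunit of replication protein A, which coats single-stranded DNA, and lies on the minus strand of chromosome 11 at 75298166 to 75348324 (GRCm38), with 18 exons in transcript Rpa1-201 of GENCODE vM21. Rpa1 was not lower in T-like cells of the library labelled CKO. In counts per 1e6 UMIs of the class (CPM) it stood at 43.9 (35.4 to 53.8, from 93 UMIs) in the library labelled WT and at 60.9 CPM (52.3 to 70.5, from 180 UMIs) in the library labelled CKO, a log2 ratio of 0.47 (0.10 to 0.85). Weighting T-like subsets alike in both libraries leaves out, here and below, the Cd8a Itgae subset, which held 2 and 69 cells. By that weighting the ratio was 0.25 (-0.14 to 0.65). This goes against the direction that the label and title imply. A 3′ tag outside a deleted part would not show a deletion, and the deleted exons are not given in the sources used here, so the transcript count does not check the label, and the libraries are named only by their labels throughout.

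In the other classes Rpa1 was 27.6 against 25.1 CPM in B-like cells, 4.35 against 7.19 CPM in plasma-like cells, 18.8 against 16.2 CPM in dendritic-like cells (DC), 12.3 against 13.96 CPM in ILC2-like cells and 13.2 against 18.99 CPM in ILC3-like cells, WT label first. NK-like cells had 2 against 88 UMIs, or 10.9 against 42.2 CPM, a log2 ratio of 1.95 (0.06 to 5.02). Neutrophil-like cells had 1 against 6 UMIs and monocyte and macrophage-like cells 0 against 27 UMIs, the latter at 4.38 CPM in the library labelled CKO, which is below the floor of 3 counts in the other library. Mast-like cells had 3 and 3 UMIs, basophil-like cells 0 and 0, fibroblast-like cells 0 and 2, and epithelial-like cells 0 and 3. Over all retained cells Rpa1 was 24.6 against 19.9 CPM. Within T-like cells it was 37.0 against 39.5 CPM in the Lef1 subset, 35.6 against 34.1 in CD4 T-like, 62.9 against 55.0 in CD8 T-like, 90.3 against 61.6 in Treg-like and 23.9 against 36.6 in gamma-delta T-like cells. It was 44.9 against 75.3 CPM in the Ikzf2 Cd7 subset, and the Cd8a Itgae subset held 0 against 40 UMIs, with 106 CPM in the library labelled CKO.

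**Figure D1:**
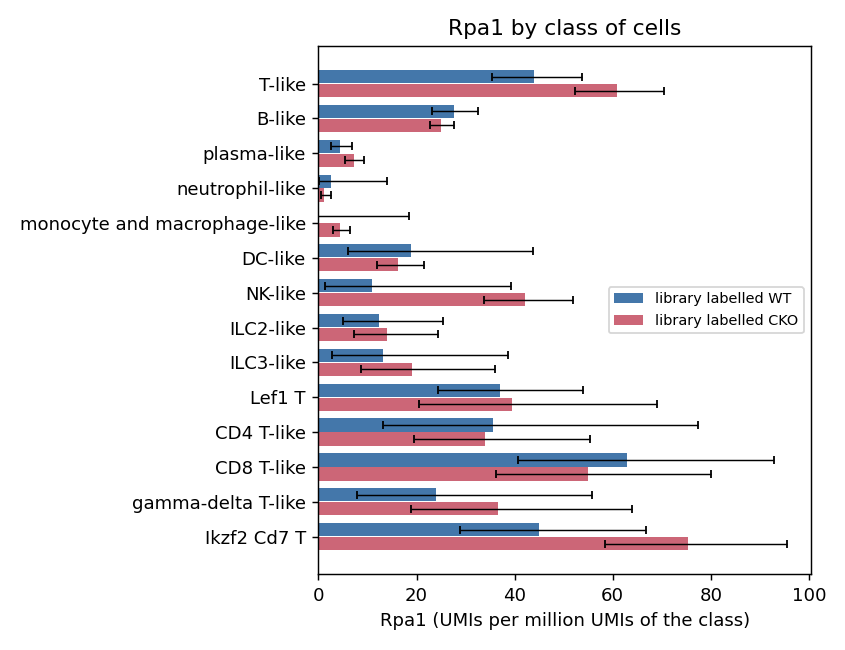
Rpa1 in CPM of the class (horizontal axis) in classes and T-like subsets (vertical axis), with bars for the libraries labelled WT and CKO and lines for exact 95% Poisson intervals, which cover counting error only. In T-like cells the bar of the library labelled CKO stands at 60.9 CPM, above the 43.9 CPM of the library labelled WT.

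The next comparison asks which immune cells were in the inflamed colon under each label. Myeloid cells took a larger share of the library labelled CKO, and T-like cells a smaller one. Neutrophil-like cells made up 6.26% (5.41 to 7.20; 183 cells) of the library labelled WT and 16.5% (15.8 to 17.2; 1803 cells) of the library labelled CKO. Monocyte and macrophage-like cells made up 0.752% (0.472 to 1.14; 22 cells) and 6.71% (6.25 to 7.19; 734 cells). T-like cells made up 12.7% (11.5 to 13.9; 371 cells) and 5.87% (5.43 to 6.32; 642 cells), a difference of -6.82 percentage points. DC-like cells were 0.889 against 2.86%, and NK-like cells 1.09 against 3.14%. Plasma-like cells were 7.18 against 4.46%, ILC2-like cells 3.49 against 2.48% and ILC3-like cells 1.20 against 0.978%. The smallest classes held 9 and 55 mast-like, 4 and 17 basophil-like, 10 and 45 epithelial-like and 3 and 44 fibroblast-like cells.

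B-like cells were the most numerous class in both libraries, at 37.5% (35.7 to 39.3; 1096 cells) and 45.7% (44.8 to 46.6; 5001 cells). The direction of the B cell share depended on the denominator. Among named immune classes alone they made up 52.4 and 51.2%, a difference of -1.28 points (-3.66 to 1.11). An unnamed cluster of few UMIs, with immunoglobulin, neutrophil and T cell transcripts in the same droplets, held 15.1% (441 cells) of the library labelled WT and 0.402% (44 cells) of the library labelled CKO. Clusters that mixed markers of different classes, kept out by a choice made after the data were seen, held 7.87 and 5.90%. Of these, mixed T and B droplets were 3.28 against 0.685%, mixed plasma 2.43 against 0.265%, mixed monocyte 1.06 against 3.35%, mixed neutrophil 0.616 against 0.978% and other mixtures 0.479 against 0.621%. An unnamed cycling cluster of the B lineage held 3.15 and 0.722%, 2 clusters of few UMIs together 1.40 and 1.67%, an unnamed Gzmc Ifng Ncr1 cluster 0.547 and 0.877%, and a cluster of digestive enzyme transcripts 1 and 30 cells. The smallest barcode totals were 501 and 500 UMIs, and of the named classes neutrophil-like cells lay closest to them, with median depths of 2059 and 2581 UMIs.

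**Figure D2:**
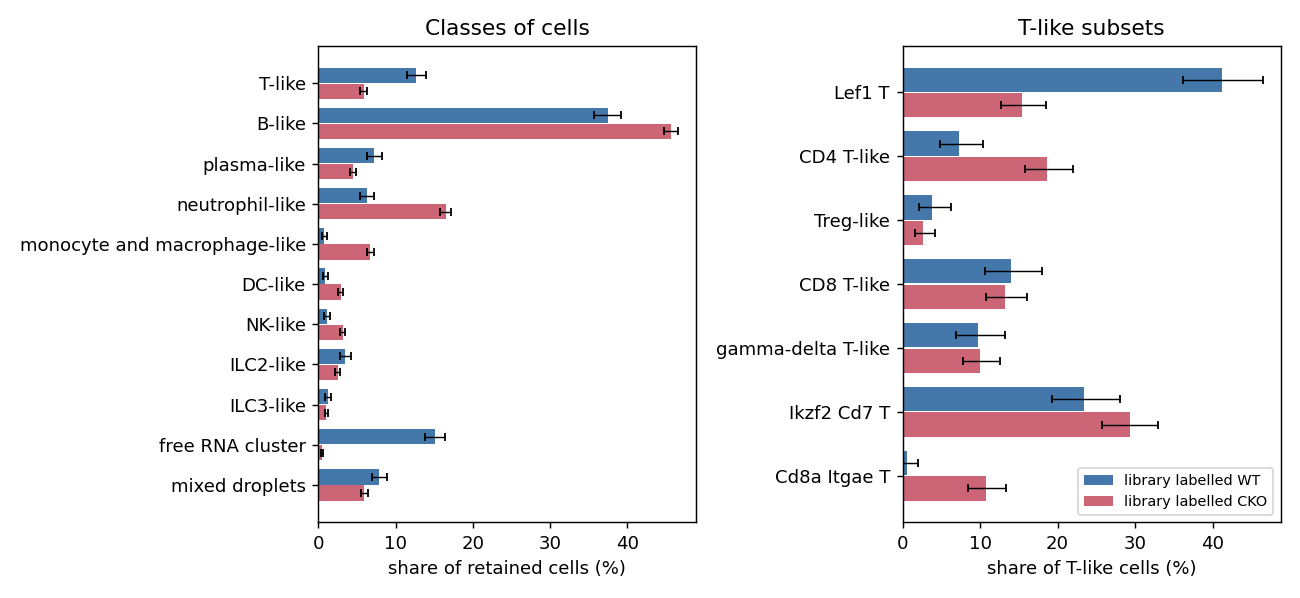
Shares of retained cells by class (left, %) and of T-like cells by subset (right, %) for the libraries labelled WT and CKO, with lines for exact 95% binomial intervals, which cover counting error only. Neutrophil-like cells stand at 6.26 and 16.5% and T-like cells at 12.7 and 5.87%, and the Lef1 subset at 41.2 and 15.4% of T-like cells.

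T-like cells were made up of different subsets under the labels. The Lef1 subset, led by Lef1, Tcf7 and Ccr7, which mark naive and central memory T cells, held 41.2% (36.2 to 46.4; 153 cells) of T-like cells in the library labelled WT and 15.4% (12.7 to 18.5; 99 cells) in the library labelled CKO. Lef1 itself was alike in those cells, at 573 and 563 CPM. Clusters were formed without leaving Lef1 out, so a like level within the subset is partly built in. CD4 T-like cells made up 7.28% (27 cells) and 18.7% (120 cells). A subset led by Cd8a, Itgae, Gzma and Klra5 without Cd8b1 held 2 cells and 69 cells, so it may be 1 library and not a type. An Ikzf2 Cd7 subset held 23.5 and 29.3%. CD8 T-like cells were 14.02 and 13.2%, gamma-delta T-like cells 9.70 and 9.97%, and Treg-like cells 3.77% (14 cells) and 2.65% (17 cells), and these 3 differences were not detectable at these cell numbers. With the Cd8a Itgae cluster counted as CD8, the CD8 share of T cells was 14.6 against 23.99%, while with each cell called by its own markers it was 30.98 against 23.83%, the opposite direction.

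Foxp3, the transcription factor of regulatory T cells, had a UMI in 1.64% and 1.59% of T-like cells when each cell was thinned to 1000 UMIs, which left out 5 and 13 shallower cells. Unthinned shares were 2.43 and 2.96%, at median depths of 4683 and 3888.5 UMIs. B-like cells, which should lack Foxp3, had 0 and 0% after thinning, at median depths of 4034 and 2940 UMIs. T-like cells with at least 2 UMIs of genes of the G2 and M phases of the cell cycle were 53.01% (47.7 to 58.2) and 58.5% (54.5 to 62.4) at that depth, and 96.8 and 95.2% unthinned. B-like cells had 53.2 and 44.9% by the same measure, so it does not separate cycling cells from others. A UMI of Mki67 or Top2a, transcripts of dividing cells, was found in 6.01 and 8.90% of thinned T-like cells and in 2.21 and 2.07% of thinned B-like cells.

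Within T-like cells, genes of effector cells that make interferon-gamma and IL-17 family cytokines were higher in the library labelled CKO, and genes of naive and recirculating T cells were lower. Ifng (ENSMUSG00000055170), the cytokine of type 1 immunity, was 49.6 CPM (40.5 to 60.0) against 767 CPM (736 to 800), a ratio of 15.5 (12.7 to 19.005). A single cell of the library labelled CKO held 1234 of its 2268 UMIs. Without the cell of most Ifng UMIs in each library the values were 44.5 against 352 CPM, a log2 ratio of 2.98 (2.68 to 3.30) in place of 3.95. The single cluster with the highest share of T-like cells was led by Lef1 and Ly6c1 in the library labelled WT (40.7% of the class) and by Ikzf2 and Cd7 in the library labelled CKO (24.9%).

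The genes named with Ifng by the fixed rule of size were Fes, a tyrosine kinase, at 8.50 against 54.1 CPM (log2 2.67), and Il18rap, a subunit of the IL-18 receptor, at 37.8 against 123 CPM (1.71). Cenpf, a centromere protein of dividing cells, was at 12.7 against 58.9 CPM (2.21). Il17f was at 30.2 against 117 CPM (1.95), with 161 of 346 UMIs in a single cell of the library labelled CKO and a ratio of 1.41 without the top cells. The serpin Serpina3g had a ratio of 1.76, the receptor Cd200r4 of 2.14 and the coronin family gene Coro2a of 1.60. Klra5 (2.28), Dapk2 (1.83), the granule protease Gzma (1.75) and the integrin Itga1 (1.71) were also named, and these 4 lead a cluster of 2 and 81 cells that came almost all from the library labelled CKO. Weighting subsets alike left out the Cd8a Itgae subset, which held 6291 of the 8480 Gzma UMIs of the library labelled CKO. By that weighting the ratios of these 4 genes were 0.72, 0.78, 0.19 and 0.95, while Ifng had 3.83, Fes 2.04, Cenpf 1.82 and Il18rap 1.49. Il17f had 1.62, which rested on gamma-delta T-like cells (40 against 321 UMIs, 2.35), since it was lower in CD4 T-like cells (-1.12). Both the 1.62 and the 2.35 include the single cell of 161 UMIs, which lies among the gamma-delta T-like cells. All 12 higher genes stayed above 0 by that weighting, with a median of 1.29.

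The 12 lower genes opened with Ifi208, an interferon-inducible gene of the HIN-200 family, at 73.2 against 7.78 CPM (log2 -3.23). Lef1, a transcription factor of naive T cells, was at 235 against 107 CPM (-1.14), and S1pr1, the receptor by which T cells leave lymphoid tissue, at 184 against 84.9 CPM (-1.12). The transcription factor Myb had a ratio of -1.49, the zinc finger gene Zfp281 of -1.49, the surface protein gene Ly6c1 of -1.47, the fatty acid elongase Elovl6 of -1.25 and the pseudokinase Trib2 of -1.15. The interferon-induced genes Ifit2 and Ifit3 had ratios of -1.16 and -1.15, and Lmo4 and Rgcc each of -1.08. Lef1, Ly6c1, Trib2, S1pr1, Elovl6 and Myb lead the Lef1 subset, and Ifit2, Ifit3 and Ifi208 lead a part of it. With subsets weighted alike, 11 of the 12 stayed below 0, with a median of -0.39, and 3 were at least 1.5 times lower: Ifi208 (-2.17), Lmo4 (-1.24) and Rgcc (-0.94). Myb (-0.58), Elovl6 (-0.55) and Zfp281 (-0.55) fell just short of that fold and were lower in every subset with at least 20 UMIs of the gene. Lmo4 and Rgcc rested on gamma-delta T-like cells (-2.11 and -2.99), and in the Ikzf2 Cd7 subset each was 0.42, while Ifi208 was lower in the Lef1 subset (-1.97), CD8 T-like (-1.89) and Ikzf2 Cd7 cells (-2.61). Lef1 was then at 0.00 and S1pr1 at -0.17, while Ly6c1 turned to 0.13. Lef1, S1pr1 and Ly6c1 lead the Lef1 subset, so this weighting cannot tell a different mix from lower levels per cell.

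**Figure D3:**
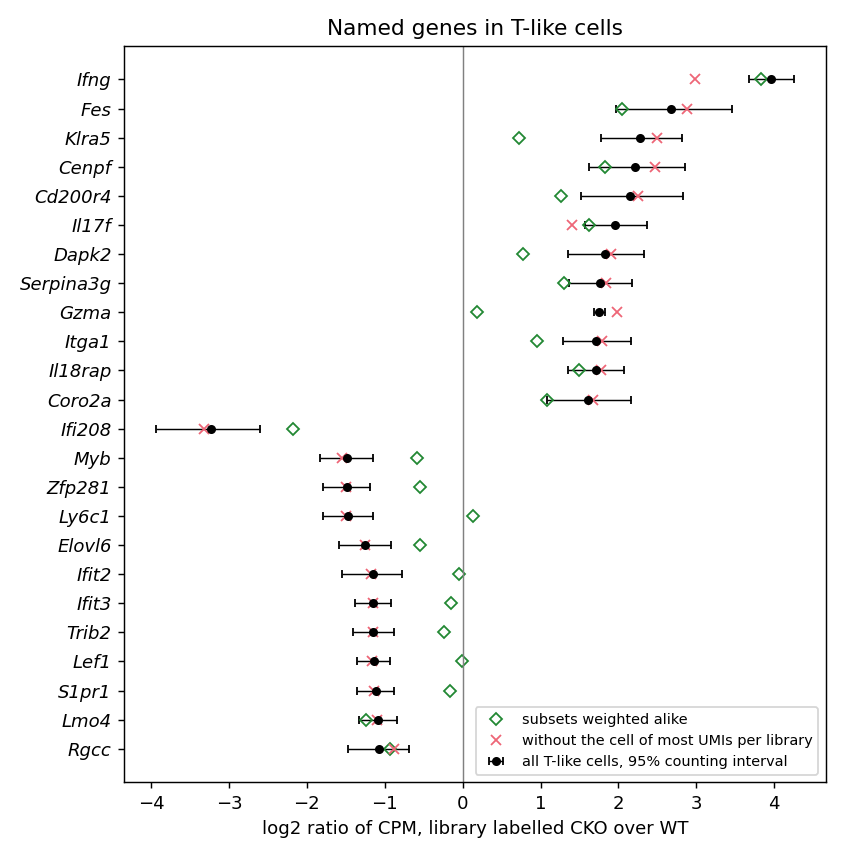
Log2 ratio of CPM in T-like cells, library labelled CKO over WT (horizontal axis), for the 12 highest and 12 lowest genes (vertical axis), over all T-like cells with exact 95% counting intervals (filled points), with subsets weighted alike (open diamonds) and without the cell of most UMIs in each library (crosses). Ifng stands at 3.95 over all T-like cells, 3.83 with subsets weighted alike and 2.98 without the top cells, while Lef1 goes from -1.14 to 0.00 with subsets weighted alike.

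Over all T-like cells the fixed gene lists of effector programmes were higher and the naive list lower, and these differences were smaller with subsets weighted alike. Each list is given as the members with at least 20 UMIs, how many of them were at least 1.5 times higher or lower in the library labelled CKO, the median log2 ratio, and the percentile of that median among 10000 random lists matched on expression, a description of these libraries. Of 13 naive and central memory genes, 0 were higher and 9 lower, with a median of -0.74 (percentile 0) and Dapl1 at -2.11, and with subsets weighted alike that median was 0.08. Genes of this list lead the Lef1 subset, so that weighting cannot tell a different mix from lower levels per cell. Of 9 Th1 genes, 6 were higher and 0 lower, with a median of 1.30 (percentile 100) and Il18r1, a subunit of the IL-18 receptor, at 1.39. Of 12 Th17 genes, 7 were higher and 0 lower, with a median of 0.82 (percentile 100), with the cytokine Il22 at 1.57 and the protease Furin at 1.52. Of 20 cytotoxic effector genes, 13 were higher and 0 lower, with a median of 0.69 (percentile 100) and the chemokines Ccl4 at 1.86 and Ccl5 at 0.97. The activation and checkpoint list had 9 of 24 higher and 1 lower, with a median of 0.53 (percentile 100), Entpd1 at 1.58 and Il2ra, the IL-2 receptor alpha chain, at 1.02. With subsets weighted alike the median was 0.94 for the Th1 list in T cells, 0.44 for the Th17 list in T cells, 0.16 for the cytotoxic effector list in T cells and 0.17 for the T activation and checkpoint list in T cells. Within subsets the median of the cytotoxic list varied, at 0.57 in Ikzf2 Cd7 and 0.83 in Lef1 cells, 1.28 in Treg-like (5 genes), 0.46 in gamma-delta T-like and 0.11 (-0.00 to 0.40) in CD8 T-like cells, against -0.35 (-0.84 to 0.03) in CD4 T-like and -0.61 in Cd8a Itgae cells, of which the library labelled WT had 2.

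The regulatory T list had 3 of 13 genes higher and 2 lower (median 0.38, percentile 98.9), with the integrin Itgae at 1.19 and the cytokine Il10 at -1.01. T cell receptor signalling (0 and 2 of 20, median 0.03, percentile 41.1) and the Th2 list (0 and 1 of 4, median 0.07, percentile 50.3) lay near the middle of matched lists. Homeostatic cytokine signalling lay lower among them (3 and 2 of 13, median -0.06, percentile 13.9). The inflammatory mediator list, read in T-like cells outside the fixed rule, had 12 of 15 genes higher and 0 lower (median 1.28, percentile 100). Chemokines, read likewise, had 5 of 7 higher and 1 lower (0.79, percentile 99.98). S100a8, a neutrophil transcript and a marker of free RNA, moved with these lists, at 11.8 against 60.2 CPM in T-like, 14.6 against 84.3 CPM in B-like and 5.27 against 33.4 CPM in plasma-like cells.

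Cell death genes were read in T-like cells because the title names necroptosis, a lytic death that runs through RIPK3 and MLKL. Over all T-like cells the necroptosis list was not set apart from matched lists: 3 of 17 members were higher and 0 lower, with a median of 0.19 (-0.04 to 0.29) at percentile 85.9. By subset, with fewer members read, the median was 0.41 in CD4 T-like (percentile 91.8) and 0.36 in Ikzf2 Cd7 cells (-0.02 to 0.63; percentile 98.6). It was 0.18 in Lef1, 0.16 in CD8 T-like, 0.16 in Treg-like, 0.01 in gamma-delta T-like and -0.15 in Cd8a Itgae cells. Mlkl, which breaks the membrane, had 4 against 21 UMIs, or 1.89 against 7.10 CPM, a log2 ratio of 1.91 (0.34 to 3.91). The kinase Ripk3 was 14.6 against 20.3 CPM (0.47; -0.18 to 1.15), Ripk1 67.5 against 53.1 CPM (-0.35; -0.68 to -0.01) and the nucleic acid sensor Zbp1 243 against 209 CPM (-0.22; -0.39 to -0.04). Ticam1 had a ratio of 1.15 and Traf2 of 0.85. In B-like cells the same list had a median of 0.16 (percentile 99.4), with 1 of 17 higher and 0 lower, and in plasma-like cells 0.02 (percentile 86.7), with 1 and 1 of 14.

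Apoptosis regulators in T-like cells had 9 of 19 genes higher and 1 lower (median 0.42, percentile 99.95), among them the BH3-only gene Bbc3 at 1.03, the death ligand Fasl at 0.94 and Apaf1 at 0.88. The pyroptosis and inflammasome list had 5 of 10 higher and 1 lower (0.60, percentile 99.9), with Casp4 at 1.55 and Gsdme at -1.58. Its top member, Il1b at 1.79, is a myeloid transcript that was also higher in B-like cells, at 26.8 against 74.6 CPM. Neither the apoptosis nor the pyroptosis list was read in single subsets, so the different mix of subsets may enter both medians. With subsets weighted alike neither median reversed, but their size by that weighting is not given here. Targets of p53, the DNA damage response factor, had 7 of 25 higher and 2 lower (0.42; 0.16 to 0.49; percentile 99.9), with Ckap2 at 1.06 and Plk2 at -0.83, and with subsets weighted alike their median was 0.13. Replication genes (5 and 2 of 35; 0.17, percentile 88.9), repair genes (11 and 4 of 38; 0.08, percentile 52.1) and S phase genes (8 and 3 of 40; 0.12, percentile 73.0) had Pold1 at 1.24, Brca1 at 1.44 and Rad51ap1 at 1.30, and the replication and S phase medians were -0.15 and -0.12 with subsets weighted alike. The G2 and M phase list in T cells had 24 of 46 higher and 0 lower (0.63, percentile 100), including Hmmr at 1.86 and Ccnb2 at 1.49, and 0.28 with subsets weighted alike. Within subsets it was -0.30 in CD8 T-like cells, 0.00 in Lef1 and 0.01 in CD4 T-like cells, 0.32 in Ikzf2 Cd7, 0.63 in Cd8a Itgae, 0.66 in gamma-delta T-like and 2.13 in the few Treg-like cells. Of the RPA complex, Rpa2 was 33.1 against 55.5 CPM (0.75; 0.34 to 1.17) and Rpa3 27.9 against 20.3 CPM (-0.46; -1.0 to 0.09), with a list median of 0.47 (percentile 94.8).

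Interferon-stimulated genes were lower over all T-like cells of the library labelled CKO. The type I interferon list had 1 of 40 genes higher and 10 lower (median -0.31; -0.39 to -0.22; percentile 0), with the antiviral synthetase genes Oasl2 at -1.05 and Oas2 at -1.01. This direction reversed with subsets weighted alike, to 0.31 (0.21 to 0.35). By subset the median was 0.44 in Lef1, 0.39 in CD4 T-like, 0.50 in Treg-like and 0.14 in CD8 T-like cells, but -0.03 in gamma-delta T-like, -0.10 in Ikzf2 Cd7 and 0.00 in Cd8a Itgae cells. The interferon-gamma response list had 1 of 23 higher and 6 lower (-0.22, percentile 0), with the GTPase genes Tgtp1 at -1.21 and Irgm1 at -0.88, and its median with subsets weighted alike was 0.20. NF-kB feedback genes had 5 of 17 higher and 0 lower (0.41, percentile 99.97), the unfolded protein list 3 of 15 and 0 (0.23, percentile 97.1), class II antigen presentation 3 of 8 and 1 (0.21, percentile 76.2) and glycolysis and hypoxia 1 of 19 and 2 (0.10, percentile 68.9). None of these lists was read in single subsets, so the different mix of subsets may enter their medians. With subsets weighted alike the NF-kB, unfolded protein and class II medians did not reverse, but their size by that weighting is not given here. Class II turned to -0.06 among cells with at least 500 genes and to -0.04 by the mean of per-cell CPM. Immediate early and dissociation stress genes had 1 of 21 higher and 6 lower (-0.15, percentile 1.56), and mitochondrial genes 0 and 0 of 13 (-0.15, percentile 6.18).

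In B-like cells the medians of both interferon lists were above 0 in the library labelled CKO, as those of T-like cells were with subsets weighted alike, and immediate early genes were lower. The interferon-gamma response list had 15 of 26 genes higher and 0 lower (median 0.61, percentile 100), with Iigp1, an immunity-related GTPase, at 1.94 and the guanylate-binding protein Gbp2 at 1.27. Its highest member, the myeloid receptor gene Fcgr4 at 1.99 (6 against 79 UMIs), moved with the myeloid transcripts S100a8 (2.53), S100a9 (1.99) and Il1b (1.48) in the same cells. The type I interferon list had 2 of 41 higher and 0 lower (0.21; 0.16 to 0.30; percentile 100), with Ifi204 at 2.59 and Ifi44 at 1.51. By the rule of size, Aldh7a1, an aldehyde dehydrogenase, was 4.20 against 52.1 CPM (log2 3.63; 3.01 to 4.33), Serpina3f 30.8 against 90.5 CPM (1.55), Gbp3 21.01 against 50.8 CPM (1.27) and Serpina3g 106 against 226 CPM (1.09). Gbp4 and Gbp7 each had a ratio of 0.98, and the cholesterol transporter Abcg1 of 0.86. Hba-a2 in B cells, a haemoglobin transcript, had 0 against 1430 UMIs, a log2 ratio of at least 7.16 at a floor of 3 counts in the library labelled WT. Those UMIs came from 17 cells, 762 of them from a single cell, without which the bound was 6.07.

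Among the lower genes of B-like cells were the AP-1 subunits Fos, at 453 against 164 CPM (log2 -1.46), and Jun, at 528 against 262 CPM (-1.01), the transcription factor Klf2, at 612 against 258 CPM (-1.25), and the heat shock genes Hspa1b (-1.10) and Hspa1a (-1.0). Plk2 (-1.31), Rhob (-1.18) and Emp3 (-0.87) completed the 8. The immediate early and dissociation stress list had 0 of 21 higher and 7 lower (-0.26, percentile 0). These genes lead some of the clusters that make up the class: Hspa1b, Hspa1a, Klf2 and Jun a cluster of 93 and 195 cells, Egr1, Egr3 and Myc a cluster of 175 and 702 cells, Gbp7, Gbp4 and Serpina3f a cluster of 40 and 641 cells, Slfn5 and Ifit3 a cluster of 124 and 740 cells, and the myeloid transcripts S100a8, S100a9 and Il1b a cluster of 144 and 521 cells. For B-like cells the single cluster with the highest share was led by Apoe, Klf2 and S1pr1 in the library labelled WT (31.2%) and by Apoe, Neurl3 and Tmem108 in the library labelled CKO (23.4%).

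The activation and germinal centre list of B-like cells had 0 of 17 higher and 2 lower (-0.09, percentile 15.4), with Rgs13 at -1.62 and Myc at -0.66. Class II genes had 0 of 10 beyond 1.5 times either way (-0.17, percentile 0.810), with H2-Ab1 at -0.25. G2 and M phase genes had 4 of 42 higher and 7 lower (-0.16, percentile 2.0), S phase genes 0 and 5 of 36 (-0.13, percentile 5.30), p53 targets 0 and 2 of 26 (-0.16, percentile 3.23) and glycolysis 0 and 1 of 19 (-0.11, percentile 9.96). The RPA complex (-0.14), replication (-0.04), repair (-0.02), apoptosis (-0.09), pyroptosis (-0.08), NF-kB feedback (0.09), unfolded protein (-0.02) and mitochondrial (0.03) lists had medians closer to 0 than the interferon-gamma list. Among these, NF-kB feedback stood at percentile 97.3 of matched lists.

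Plasma-like cells, which secrete antibody, were higher in the library labelled CKO for Pon3 (25.9 against 57.9 CPM, log2 1.16), the serpins Serpina3f (1.15) and Serpina3g (0.96), the co-chaperones Dnajb1 (1.06) and Dnaja1 (0.73), Mzb1, a chaperone of antibody assembly (1440.1 against 2328 CPM, 0.69), the checkpoint receptor Ctla4 (0.63) and D10Wsu102e (0.56). Lower were Klf2 (143 against 51.1 CPM, -1.49), the protease inhibitor Slpi, the linker histone Hist1h1e (-1.06), the sterol pathway enzyme Fdps (-1.06), Tagln2 (-0.99), Vim (-0.91), Klf13 (-0.89) and Plp2 (-0.88). Slpi was 1539 against 550 CPM (-1.49), with 926 of its 6716 UMIs in the library labelled WT from a single cell and a ratio of -1.33 without the top cells. Another scaling, median of ratios, raised all ratios of this class by 0.11.

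Of the lists in plasma-like cells, the interferon-gamma response had 5 of 21 genes higher and 3 lower (median 0.26, percentile 100), with Gbp6 at 1.14 and Gbp4 at 1.01, against Cxcl10 at -1.31. The type I interferon list had 2 of 34 higher and 8 lower (-0.33, percentile 0), with Ifit1 at -1.83 and Ifit3 at -1.18. The unfolded protein list, whose genes support secretion, had 0 of 18 higher and 2 lower (-0.25, percentile 0.250), with Trib3 at -1.74 and Chac1 at -0.88. Repair genes had 0 and 4 of 28 (-0.31, percentile 2.16), replication genes 0 and 6 of 26 (-0.22, percentile 9.49), immediate early genes 3 and 5 of 21 (-0.19, percentile 3.73) and glycolysis 3 and 4 of 18 (-0.26, percentile 2.20). In the glycolysis list Egln3, at -4.68, rested on 43 against 3 UMIs, with 36 of the 43 in a single cell. Replication turned to 0.25 without doublet removal. The medians of S phase (0.08), G2 and M phase (-0.08), p53 (-0.03), RPA complex (0.05), apoptosis (-0.12), pyroptosis (-0.18), class II (-0.03), NF-kB (0.00) and mitochondrial (-0.06) lists were closer to 0, and the last turned to 0.05 by median of ratios and to 0.04 by per-cell CPM. Among these, S phase stood at percentile 96.4 of matched lists, whose own median was -0.09.

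**Figure D4:**
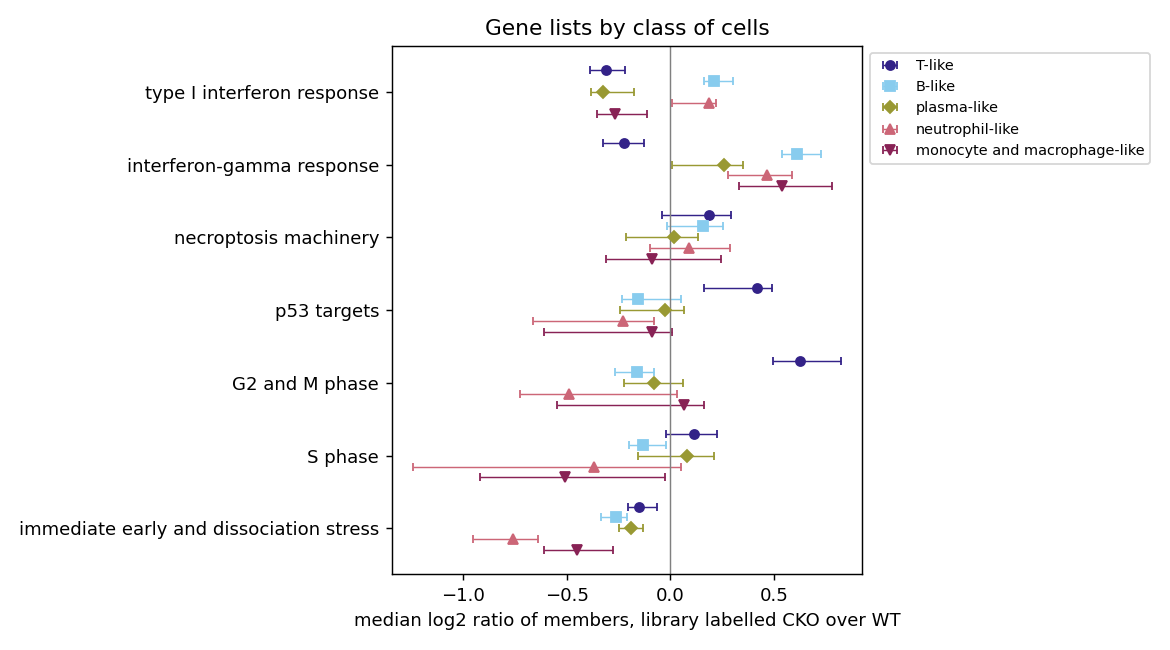
Median log2 ratio of list members, library labelled CKO over WT (horizontal axis), for 7 gene lists (vertical axis) in 5 classes, with lines for the 95% interval from Poisson redraws of the counts, which cover counting error only. The type I interferon list stands at -0.31 in T-like and 0.21 in B-like cells, and the interferon-gamma list at -0.22 and 0.61.

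Neutrophil-like cells of the library labelled CKO held far more transcripts of granule proteins, which neutrophils make before they leave the bone marrow. The granule and maturation list had 9 of 16 genes higher and 1 lower (median 1.08; 0.88 to 1.60; percentile 100). Ngp, a specific granule protein, had 5 against 3275 UMIs (log2 5.63), the cathelicidin Camp 1 against 482 UMIs (5.19), Cd177 6 against 741 UMIs (3.23) and the collagenase Mmp8 44 against 4914 UMIs (3.08). Ngp, Camp, Cd177 and Mmp8 lead a cluster of 1 and 220 cells, Retnlg and Mmp8 a cluster of 2 and 216 cells, and Ifit1, Cxcl10 and Rsad2 a cluster of 14 and 393 cells, so these may be 1 library. For neutrophil-like cells the single cluster with the highest share was led by Ccl3, Csf1 and Cxcl2 in the library labelled WT (44.3%) and by G0s2 and Csf3r in the library labelled CKO (25.2%).

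The inflammatory mediator list in neutrophil-like cells had 9 of 21 genes higher and 6 lower (0.37; -0.01 to 0.51; percentile 99.85). Nos2, which makes nitric oxide, had 1 against 368 UMIs (4.80), the iron-binding protein Lcn2 a ratio of 1.77, Inhba of -1.45, and Ifng, with 19 against 33 UMIs, of -2.92, from 47.6 CPM in the library labelled WT, near the 49.6 CPM of its T-like cells. Transcripts of other cells were lower with it: class II genes had 0 of 9 higher and 7 lower (-1.06, percentile 0.03), Igha was at -1.34 and Jchain at -1.71. The interval of the inflammatory list includes 0, median of ratios put the median at 0.62, and that scaling raised all ratios of this class by 0.25. Chemokines had 1 of 12 higher and 7 lower (-0.79, percentile 0.280), with Ccl2 at -1.82 and Ccl3 at -1.18. Immediate early and dissociation stress genes, which cell preparation can alter, were lower alike, with 0 of 21 higher and 14 lower (-0.76, percentile 0.03). That list and class II were among those read in this class outside the fixed rule. So was the interferon-gamma response list, with 9 of 23 higher and 1 lower (0.47, percentile 100). The alternatively activated macrophage list had 1 and 3 of 6 (-0.63, percentile 8.82), with Chil3 at 2.38 and Vegfa at -2.33.

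Monocyte and macrophage-like cells numbered 22 in the library labelled WT, so values within them are coarse. The inflammatory mediator list had 13 of 23 genes higher and 0 lower (0.67; 0.37 to 0.76; percentile 100), with the acute phase gene Saa3 at 2.09, the cytokine subunit Il23a at 1.42 and Il12a, with 2 against 192 UMIs, at 1.63 (-0.24 to 4.69). With the highest doublet scores removed the median was 0.31, and by per-cell CPM 0.86. The alternatively activated and resident macrophage list had 6 of 12 higher and 1 lower (0.52; -0.05 to 0.80; percentile 99.5), with the arginase Arg1 at 0 against 225 UMIs, a log2 ratio of at least 1.28, and the elastase Mmp12 at -2.33. Chemokines had 2 of 16 higher and 6 lower (-0.10; -0.25 to 0.10; percentile 28.6), with Ccl7 at -1.78, and immediate early and dissociation stress genes 1 of 21 higher and 9 lower (-0.45, percentile 0). The latter list was read here outside the fixed rule. So was the interferon-gamma response list, with 13 of 26 higher and 2 lower (0.54, percentile 100). The granule list had 4 of 12 higher and 3 lower (0.24, percentile 98.6), with Retnlg at 2.37 and Prtn3 at 2.58. Nos2, Cxcl9 and Inhba lead a cluster of 5 and 275 cells, Vcan and Chil3 a cluster of 13 and 332 cells, C1qa a cluster of 4 and 100 cells and Prg4 a cluster of 0 and 27 cells. Median of ratios raised all ratios of this class by 0.11.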

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

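All alternative settings chosen before the data were examined were run; those on the free RNA cluster, mixed droplets, the Cd8a Itgae cells, highest doublet scores, subsets weighted alike and top cells were chosen after the data were seen, as was every alternative for named genes and for lists outside the first choice. No paired analysis was possible because each group has 1 library. Of 111 values of the main results under an alternative, 89 stayed within the counting interval, 20 left it and 2 with an interval off 0 reversed; of 472 for named genes, 440, 31 and 1; of 451 for other lists, 398, 45 and 8; and all 45 for other shares stayed within it. Among immune classes only, the difference in the T cell share was -11.2 points and in the B cell share -1.28, a reversal. Without the free RNA cluster they were -9.05 and 1.75. With mixed droplets counted, T was -9.42 and monocyte and macrophage 8.25. With cells called by their own markers, neutrophil was 11.7, monocyte and macrophage 6.55, B 0.890 and the CD8 share of T cells -7.15. Without doublet removal, monocyte and macrophage was 6.55 and plasma DNA replication reversed to 0.25. At 500 genes or more, B was 4.04 and the antigen presentation class II list in T cells reversed to -0.062. At resolution 2, Treg was 3.06, and with Cd8a Itgae cells counted, CD8 was 9.43. The cycling share was -1.59 without thinning and -3.62 with subsets weighted alike. Treg at resolution 2, CD8 with those cells counted and both cycling values also changed sign, from intervals that included 0. Subsets weighted alike also gave p53 targets 0.13 and reversed type I interferon (0.31), Ly6c1 (0.13), the naive and central memory T list in T cells (0.078), DNA replication (-0.15) and the interferon-gamma response (0.20) in T cells. The inflammatory list was 0.62 in neutrophils and 0.78 in monocytes and macrophages by median of ratios, and in the latter 0.31 with the highest doublet scores removed and 0.86 by per-cell CPM. Per-cell CPM reversed class II to -0.038 and the mitochondrial encoded list in plasma cells to 0.036, and median of ratios the latter to 0.052. Rpa1 in T cells stayed above 0, from 0.25 to 0.60. Why settings moved values was not tested.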

Other observations

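In this part, the tests on named immune classes, subsets weighted alike, B-like cells and the T to B ratio, and the value without the top cell, were chosen only after the result was seen, and the first 2 paragraphs are readings outside the chosen comparisons. Some cytokines of innate lymphocytes differed between the labels, while others were alike. An unnamed lymphoid cluster led by Gzmc, Ifng and Ncr1 (16 and 96 cells) had Ifng at 331 against 11419 CPM (log2 5.11) and Csf2, a myeloid growth factor, at 55.2 against 397 CPM (2.85), but Il22, a cytokine that acts on epithelium, at 3521 against 685 CPM (-2.36). NK-like cells had Ifng at 1989 against 3127 CPM (0.65), with Ccl4 (-1.59), Ccl3 (-1.16) and Gzmb (-1.12) lower and the inhibitory receptor Klrg1 (1.39) higher, and a cytotoxic list median of -0.27. These rest on 32 cells of the library labelled WT, and markers of other cells were lower with them: Cd3e of T cells at 54.5 against 18.2 CPM (-1.58), Igha at -1.50 and Jchain at -1.64. ILC2-like cells, which make type 2 cytokines, had Il5 at 1284 against 679 CPM (-0.92), Il13 at 634 against 321 CPM (-0.98), Csf2 at 918 against 332 CPM (-1.47) and Areg, a tissue repair factor, at -0.58. Il22 in ILC3-like cells was alike, at 33437 and 34989.5 CPM.

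Fos, an immediate early gene, was lower in the library labelled CKO in T-like (-0.92), B-like (-1.46), neutrophil-like (-1.41), DC-like (-1.41), NK-like (-2.05), ILC2-like (-0.91) and ILC3-like cells (-1.44). Ifi208 was lower in B-like cells too, at 39.0 against 7.35 CPM (-2.41), and in neutrophil-like cells with 15 against 2 UMIs (-6.63; -9.80 to -4.52). Aldh7a1, at 3.63 in B-like cells, was -0.07 in T-like and 0.25 in plasma-like cells. Reg3b, an epithelial antimicrobial gene, had 3 against 105 UMIs in T-like and 7 against 593 UMIs in B-like cells (4.67). Ighg1 in plasma-like cells had 4176 against 50 UMIs, 2130 of the 4176 in a single cell.

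Neutrophil and monocyte shares were higher in the library labelled CKO. Unnamed and mixed droplets as mere fillers of the WT total are argued against: among named immune classes neutrophil-like cells were 8.76 against 18.4%, a difference of 9.69 points (8.19 to 11.1). Whether the cluster of few UMIs with neutrophil transcripts (441 and 44 cells) held neutrophils was not tested, and leaving it out cannot tell. Among cells with at least 5000 UMIs, monocytes and macrophages were 1.72% of 1106 and 18.2% of 3163, a difference of 16.5 points (14.9 to 18.1). That cannot decide on missed cells of few UMIs. The class was deep (medians 9710.5 and 8403.5 UMIs), so losing shallow cells would not lower its share. In a further reading, neutrophil-like cells were 4.14% of 2343 and 13.8% of 9383 cells with at least 2000 UMIs, a difference of 9.67 points (8.55 to 10.7). That cut lay near their own median depths, so shallower ones were not covered. The label, the animals and the cell preparation stay open and untested, since each label has 1 library.

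The type I interferon list was lower over all T-like cells of the library labelled CKO. Free RNA of the whole library would lower the list in other classes too. In B-like cells the median was 0.21 (0.16 to 0.30), while it was lower in plasma-like (-0.33, -0.38 to -0.18) and monocyte and macrophage-like cells (-0.27, -0.36 to -0.11). The interferon-gamma response list was also higher in B-like cells (0.61). A rise of their own could thus hide a fall, so these values cannot decide on free RNA. With T-like subsets weighted alike the median was 0.31 (0.21 to 0.35), so a different mix of subsets may account for the lower value, a hypothesis from the same data. Whether the label underlies that mix was not tested.

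Ifng was higher in T-like cells of the library labelled CKO. Free RNA is argued against by a T to B ratio of 137 (111 to 170; 767 against 5.60 CPM, and 352 CPM in T-like cells without the top cell), and NK cells among T cells by a log2 ratio of 4.45 (4.11 to 4.80; 3.30 without the top cells) in the 323 and 484 cells with a Cd3 UMI and no NK marker UMI. A different mix of subsets is argued against by 3.83 with subsets weighted alike (2.89 without the top cells). CD8 T-like cells held 1581 of the 2268 UMIs, though 1234 of these came from a single cell, and the Ikzf2 Cd7 subset held 423. CD4 T-like cells were close, at 142 against 170 CPM. A few cells as the cause of the direction are argued against by a difference of 6.01 points (2.95 to 8.87) in the share of T-like cells with an Ifng UMI at 1000 UMIs, 2.73 against 8.74% (unthinned 9.43 and 17.6%; B-like 0.461 and 0.689%), though a single cell may set much of the size, which was 2.98 (2.68 to 3.30) without it; the label, animals and preparation stay open, since each label has 1 library.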
